A study of Xenopus laevis with 32 samples.

How the data were processed

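Bulk RNA sequencing of amputated Xenopus laevis tails was analysed in 32 libraries. Per the labels' protocols, each sample held total RNA of 20 embryos, 100 ng of it went into the Lexogen SENSE Total RNA-Seq kit, and the pooled libraries were sequenced on an Illumina NextSeq 500 as 2x76 bp reads. The labels give the tissue (tail), the period (regeneration or refractory) and the time after amputation (0, 0.5, 6 or 72 h). They describe 4 biological repeats, which the titles mark with the letters A to D. Each of the 8 groups of period and time therefore held 4 libraries.

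Per the submitters' processing notes, the tools were STAR 2.7.9a, HTSeq 0.6.1p1, DESeq2 1.32.0 and R 4.1.0, with no order or settings. The genome build and the annotation are not given in the sources used here, so no gene positions are reported. The deposited raw tables, 1 per period, hold read counts per gene, with no normalization, and list genes with a count in at least 2 libraries of the table. The authors' normalized tables, also 1 per period, hold a signal: each column equals the raw counts of that library divided by 1 size factor. These 2 tables hold 13 regeneration and 14 refractory libraries. The 5 libraries they lack are regeneration 0 h A, regeneration 0.5 h A, regeneration 6 h B, refractory 0.5 h A and refractory 72 h A, and the sources used here give no reason. All 59 columns of the 4 tables were matched to samples by their titles. A line without values in each table was not used.

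The raw counts were used for every test. The tables list 28490 genes for regeneration and 28280 for refractory tails, and the 27467 genes listed in both were analysed. The 1023 and 813 genes listed for a single period took 0.0217% and 0.0205% of that period's counts. Gene symbols are those of the tables, and 29300 of the 29303 identifiers match a RefSeq symbol. The endings .L and .S mark the homeolog copies of a gene in this allotetraploid frog. Genes that share reads with a near-identical homeolog are uncertain, because how shared reads were assigned is not stated.

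Tests were run in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, low-count genes were removed with filterByExpr by group, and 1 quasi-likelihood model (glmQLFit, robust, and glmQLFTest) was fitted to the 8 groups over all 32 libraries. It tested 21231 genes with 24 residual degrees of freedom at a common biological coefficient of variation of 0.38. There were 10 contrasts: each later time against 0 h within each period, the difference between the periods' responses at each later time (refractory minus regeneration), and refractory 0 h against regeneration 0 h. P-values were adjusted by Benjamini-Hochberg within each contrast, and genes with an adjusted p under 0.05 were called. All adjusted p-values of genes come from this edgeR model unless another is named, are two-sided, and measure the spread between samples as labelled. Expression is given in CPM, the counts scaled by edgeR's cpm function to TMM-adjusted library sizes, as mean ± SD of 4 libraries. Log2 changes carry the standard error (SE) of the fit.

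The 23 gene lists, the rule for named genes, the contrasts, the tests and the alternative settings were chosen before the data were examined. The lists were immediate early and early response; heat shock and endoplasmic reticulum stress; inflammatory mediators; myeloid leukocyte markers; matrix proteases and wound matrix; regeneration-organizing tail tip epidermis, TGF-beta, activin and BMP signalling, Wnt, FGF, Notch and Hedgehog signalling, cell cycle, skeletal muscle, notochord, spinal cord and neuronal, epidermis and goblet cell, multiciliated cell and ionocyte, mesenchyme and collagen matrix, endothelial, erythroid and pigment cell markers, posterior patterning factors, glycolysis and hypoxia, oxidative phosphorylation, markers of liver, pancreas and gut, and lymphoid and interferon response. A gene belongs to a list when its symbol without .L or .S equals an entry, and each measured homeolog counts as 1 member. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over all 230 tests of 23 lists and 10 contrasts. The same tests with a correlation estimated from the data are given beside them. Members called over all genes tested are given beside those called when adjusted over the list alone. List medians were also computed with genes that had almost no counts in 1 group set to their bound, which moved none of 161 medians by more than 0.069.

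The rule for named genes took, for each later time in each period, the 8 genes with the largest rise and the 8 with the largest fall among called genes that have a symbol, a mean of at least 5 CPM in 1 group and no overlap between the libraries of both groups. For each difference between the periods it took 6 and 6 without the overlap condition. It added up to 3 called members of each list per contrast, and a panel of 12 symbols of which 15 genes were measured. Where all libraries of a group held 0 counts, the fold is a lower bound computed against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

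Total counts per library ran from 1868637 to 4022871, with a median of 3026459.5. A floor of 3 counts is 1.61 CPM in the shallowest library and 0.746 CPM in the deepest. The procedure was tested on simulated data: of 200 genes changed in a comparison shaped like regeneration 6 h against 0 h, 36% of 2-fold and 86% of 4-fold changes were called, 3 of 125 calls were of unchanged genes, and no gene was called in a comparison without changes. The changed genes were drawn from those with a mean of at least 5 CPM. Simulated genes varied independently, with no library that stood apart as a whole, so these shares need not hold for the real libraries. Pairs of libraries of the same group were compared for duplicates, and none were found among 48 pairs.

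Alternatives were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, an adjusted p under 0.01, a 2-fold minimum, homeologs summed, fits of only the groups compared or of 1 period's 16 libraries, the replicate letter as a block, and each library left out in turn. A fit of the 27 libraries of the authors' normalized tables (21458 genes tested, 19 residual degrees of freedom) was added after seeing the data. The labels do not say what a shared letter marks, so the letters were not used as blocks in the report's tests. Marker genes of retina and lens, and of forebrain and midbrain, were listed after seeing the data and summed per library in CPM. The position of a library between the periods is the median, over genes called at 0 h in the fit of 27 libraries with at least 20 CPM in 1 of the 0 h groups, of its log2 distance from the regeneration 0 h mean as a percentage of the distance to the refractory 0 h mean.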

Results

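Gene expression was measured in tails of Xenopus laevis embryos at 0, 0.5, 6 and 72 h after amputation, in the regeneration period and in the refractory period, a phase of development in which an amputated tail does not regrow. Each of the 8 groups held 4 libraries, A to D, each from 20 embryos. No group held unamputated tails of a later time, so changes from 0 h include any normal development over the same hours. The extraction protocol gives the regenerative stage for every sample, those labelled refractory included, so refractory here is the period named in the labels, and the stage of these embryos is not settled. Total counts per library ran from 2646237 to 3892535 at regeneration 0 h, from 2708505 to 3398109 at 0.5 h, from 2805286 to 4015110 at 6 h and from 2973530 to 4022871 at 72 h. In the refractory period they ran from 2130840 to 3100089 at 0 h, from 1868637 to 3567797 at 0.5 h, from 2011011 to 3283790 at 6 h and from 2680015 to 3468181 at 72 h. The authors' normalized tables lack 5 of the 32 libraries. Of these, regeneration 0 h A, regeneration 0.5 h A, regeneration 6 h B and refractory 72 h A stood apart from the rest in the summed counts of retina and lens genes and of liver, pancreas and gut genes, as described with the plot of those sums. The number of called genes is therefore given for all 32 libraries and for the 27 libraries of the normalized tables, the latter chosen after seeing the data. Members of lists are given for 32 libraries, and also for 27 where the number called moved by 5 or more.

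**Figure D1:**
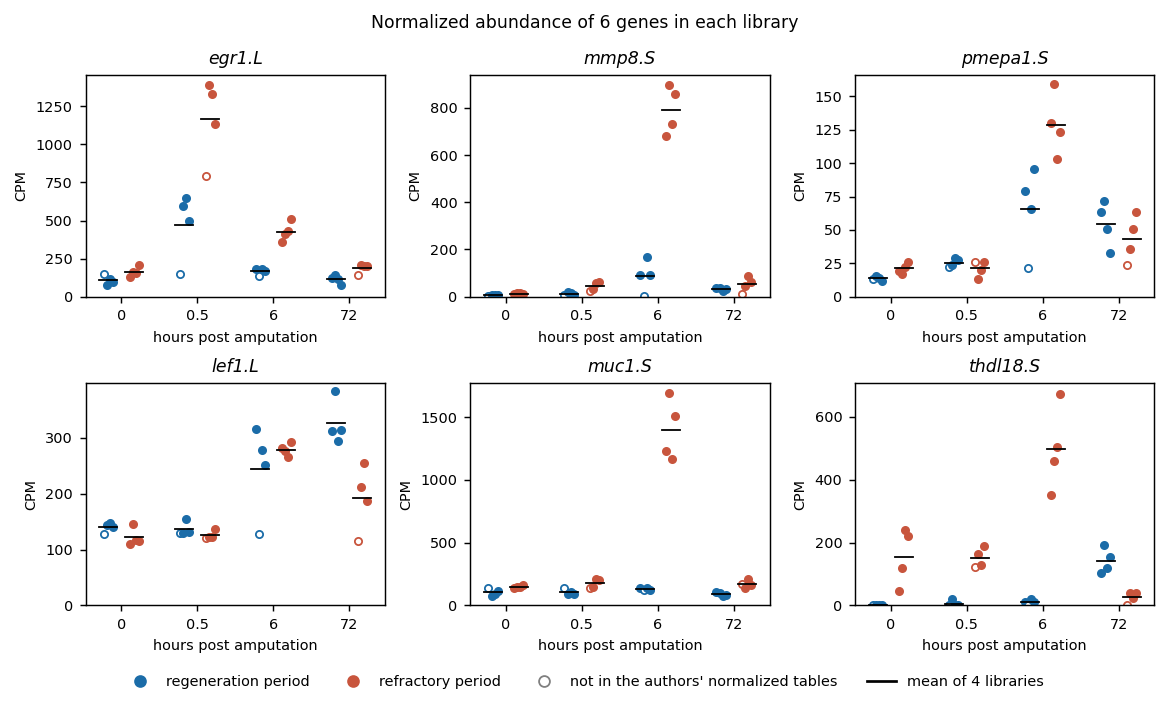
Expression in CPM of 6 genes in each of the 32 libraries by hours after amputation, with regeneration in blue and refractory in red, open circles for the 5 libraries absent from the authors' normalized tables and a line at the mean of the 4 libraries of each group. In regeneration 6 h B mmp8.S stood at 4.03 CPM beside a group mean of 89.4 CPM, and muc1.S reached a mean of 1401 CPM in refractory tails at 6 h and 130.5 CPM in regeneration tails.

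The first comparison asked what changed within 0.5 h of amputation in the regeneration period. Immediate early genes rose. The transcription factor genes egr1.L (473 ± 225 CPM against 110 ± 31.2 at 0 h, SD, n = 4; log2 change 2.1 ± 0.31 SE, adjusted p = 0.00284) and klf2.S (54.5 ± 30.2 against 8.83 ± 1.86 CPM, adjusted p = 0.000456) were higher, and jun.L, an AP-1 subunit gene, rose by a log2 change of 0.92 ± 0.14. Among the genes called, the AP-1 subunit gene fos.L rose by 4.30 ± 0.68 (102 ± 65.7 against 5.37 ± 3.7 CPM, adjusted p = 0.00644), while its homeolog fos.S was not called (4.81 ± 0.99, adjusted p = 0.0817). The gene of the secreted chaperone clusterin, clu.L, rose from 0.25 ± 0.5 to 5.46 ± 0.88 CPM (adjusted p = 0.00086), a level close to the floor of a single library.

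In all, 13 genes were called at regeneration 0.5 h, all higher, and 28 in 27 libraries (27 higher, 1 lower), 11 of them in both fits. Of the 77 measured members of the immediate early list 8 rose, and 25 when adjusted over the list alone (median log2 change 0.35, adjusted p = 3.83e-26, and adjusted p = 0.0128 with an estimated correlation). Inflammatory mediators passed the list test with none of 28 members called (median 0.23, adjusted p = 0.0289, and adjusted p = 0.204 with an estimated correlation). Skeletal muscle markers tested lower with none of 86 called (median -0.15, adjusted p = 0.00103, and adjusted p = 0.52 with an estimated correlation), and erythroid markers tested higher with none of 29 called (median 0.35, adjusted p = 0.00173, and adjusted p = 0.442 with an estimated correlation). The count depends on single libraries: it was 21 without 0.5 h A, 4 without 0 h B, 6 without 0.5 h B, 6 without 0 h C, 7 without 0.5 h C and 6 without 0 h D. The calls of egr1.L, klf2.S, jun.L and clu.L remained under each omission, while fos.L lost its call without 0 h B (adjusted p = 0.0853). Fewer genes were called by fits of only the groups compared or of the period's libraries, as given with the processing. In the fit of the period's libraries not all calls that remained under omissions hold. Of the lists 1 held with an estimated correlation, and with 27 libraries 4 passed upward and 2 downward and 2 held. In those 27, 18 of 78 immediate early genes rose. In 0.5 h A, fos.L stood at 7.25 CPM.

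Immediate early genes rose in the refractory period too. Of the AP-1 genes, fos.L rose from 6.00 ± 4.17 to 259 ± 42.6 CPM (log2 change 5.47 ± 0.70, adjusted p = 8.55e-05), junb.S from 18.9 ± 3.19 to 144 ± 30.6 CPM (adjusted p = 0.000735) and jun.S from 273 ± 20.4 to 688 ± 93.8 CPM (adjusted p = 8.15e-13). Of the zinc finger transcription factor genes, egr1.L reached 1164 ± 269 CPM from 164 ± 32.2 (adjusted p = 1.16e-05) and klf2.S 142 ± 35.8 from 15.5 ± 6.64 CPM (adjusted p = 1e-06). The mRNA decay factor gene zfp36.S rose by a log2 change of 1.27 ± 0.12 (adjusted p = 1.66e-11). Mediators of inflammation also rose: the prostaglandin synthase gene ptgs2.L by 1.80 ± 0.28 (adjusted p = 0.000417) and the transcription factor gene cebpd.L by 1.1 ± 0.16 (adjusted p = 7.72e-05).

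At refractory 0.5 h 28 genes were called, all higher, and 66 in 27 libraries (64 higher, 2 lower), including all 28. Of 77 immediate early genes 18 rose, and 44 when adjusted over the list alone. Immediate early genes had a median log2 change of 0.99 (adjusted p = 2.55e-72, and adjusted p = 7.99e-05 with an estimated correlation). Of 28 inflammatory mediators 3 rose, and 3 when adjusted over the list alone. Inflammatory mediators stood at a median log2 change of 0.20 (adjusted p = 2.89e-05, and adjusted p = 0.0222 with an estimated correlation). Matrix proteases and wound matrix genes passed with 1 of 64 members called, adamts1.L, a call lost in 6 of 8 omissions with adjusted p up to 0.517 (median 0.07, adjusted p = 0.0305, and adjusted p = 0.643 with an estimated correlation). Of the lists 2 held with an estimated correlation, and with 27 libraries 3 passed upward and 1 downward and 2 held. In those 27, 33 of 78 immediate early genes rose. Without 0 h A 18 genes were called, and the 8 omissions ranged from 18 to 26.

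Whether the periods differed in this first response was tested as the difference of their changes. With edgeR 0 genes were called in 32 and 0 in 27 libraries, where 706 and 1024 genes had an unadjusted p under 0.05. DESeq2 also called 0, with 981 genes at an unadjusted p under 0.05. Leaving out regeneration 0 h B gave 1 gene. As a group, immediate early genes differed in the direction of a larger refractory rise, with none of 77 called and 3 when adjusted over the list alone. Together the genes had a median difference of 0.52 (adjusted p = 2.24e-08, and adjusted p = 0.168 with an estimated correlation). Erythroid markers differed downward with none of 29 called (median -0.59, adjusted p = 0.00319, and adjusted p = 0.461 with an estimated correlation). At 0 h these markers already stood higher in refractory tails (median log2 difference 0.81). Of the lists, 2 passed upward and 2 downward and none held with an estimated correlation, and with 27 libraries 3 and 2 passed and none held. Across the 34 genes called in either period the log2 changes of the periods correlated at r = 0.457 and 97.1% had the same sign. Over all 21231 genes r was 0.036 (Spearman 0.015), 0.017 without regeneration 0.5 h B and 0.024 without regeneration 0.5 h C. These correlations are across genes, which are not independent replicates. Of the called genes 7 rose in both periods, where lists independent of each other would share 0.02.

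**Figure D2:**
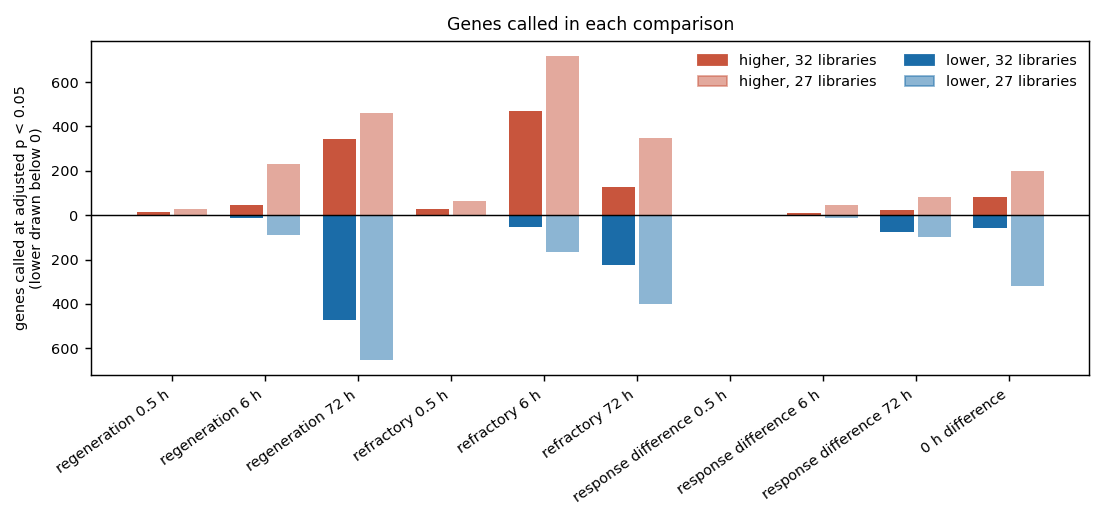
Number of genes called higher (bars above 0) and lower (bars below 0) at an adjusted p under 0.05 in each of the 10 contrasts, dark for the fit of 32 libraries and pale for the 27 libraries of the authors' normalized tables. At 6 h 58 genes were called in regeneration and 520 in refractory tails with 32 libraries, and 323 and 886 with 27.

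At 6 h in the regeneration period, single genes that remodel matrix and single genes of TGF-beta signalling were higher. The matrix metalloproteinase genes mmp1.S (147 ± 101 against 1.63 ± 1.46 CPM, log2 change 6.59 ± 1.05, adjusted p = 0.00447) and mmp9.2.L (71.9 ± 57.6 against 1.28 ± 1.56 CPM, adjusted p = 0.00754) were higher. Both homeologs of pmepa1, a TGF-beta target gene that restrains the pathway, rose: pmepa1.S by 2.25 ± 0.32 (adjusted p = 0.00043) and pmepa1.L by 1.41 ± 0.24 (adjusted p = 0.0031). The neuronal pentraxin gene nptx1.L rose by 4.57 ± 0.78 (adjusted p = 0.00164). The Wnt effector gene lef1.L rose from 141 ± 8.37 to 244 ± 81.4 CPM (adjusted p = 0.035). Its homeolog lef1.S, at 65.5 ± 9.81 and 73.8 ± 20.3 CPM, was not called. Lower were dennd4b.L (-1.03 ± 0.19, adjusted p = 0.00397) and the muscle genes smyd1.L (-0.77 ± 0.18, adjusted p = 0.034) and myoz2.S (-0.57 ± 0.14, adjusted p = 0.0483).

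The test called 58 genes (47 higher, 11 lower) with 32 libraries and 323 (233 higher, 90 lower) with 27, including all 58. Of 64 matrix protease and wound matrix genes 10 rose, and 17 when adjusted over the list alone. Matrix protease genes had a median log2 change of 0.28 (adjusted p = 5.38e-06, and adjusted p = 0.284 with an estimated correlation). Of 77 immediate early genes 4 rose, and 24 when adjusted over the list alone. Immediate early genes stood at a median log2 change of 0.53 (adjusted p = 8.97e-17, and adjusted p = 0.0628 with an estimated correlation). Of 53 TGF-beta, activin and BMP genes 2 rose, and 5 when adjusted over the list alone. TGF-beta, activin and BMP genes together had a median of 0.13 (adjusted p = 0.0102, and adjusted p = 0.0738 with an estimated correlation). Of 62 epidermis and goblet cell markers 1 rose, lamb3.S, which codes for a laminin chain, and 6 when adjusted over the list alone. Epidermis and goblet cell markers had a median log2 change of 0.24 (adjusted p = 4.05e-08, and adjusted p = 0.267 with an estimated correlation). Of 86 muscle markers 2 fell, and 4 when adjusted over the list alone. Muscle markers stood at a median log2 change of -0.31 (adjusted p = 6.17e-12, and adjusted p = 0.146 with an estimated correlation). In all 10 lists passed and none held with an estimated correlation. With 27 libraries 6 held: immediate early genes, inflammatory mediators, matrix proteases, tail tip epidermis, TGF-beta signalling and epidermis, with adjusted p from 0.000535 to 0.0365 with an estimated correlation. In the 27 libraries 22 of 78 immediate early genes, 11 of 62 epidermis and goblet cell markers and 6 of 44 tail tip epidermis genes (1 of 43 with 32 libraries) rose, and 7 of 87 muscle markers fell. Library 6 h B lay far from its group, with mmp1.S at 1.01 and mmp9.2.L at 4.03 CPM. The count was 229 without 6 h B, 19 without 6 h A, 16 without 0 h B, 22 without 0 h C, 12 without 6 h C, 19 without 0 h D and 26 without 6 h D. Of the named genes, mmp1.S, mmp9.2.L, nptx1.L, both pmepa1 homeologs and dennd4b.L kept their calls under each omission, whereas lef1.L, lamb3.S, smyd1.L and myoz2.S lost theirs in 6 or 7 of 8, with adjusted p up to 0.284. Fits of only the groups compared and of the period's libraries called fewer genes, as given with the processing. Not all of the calls kept under omissions hold in the fit of the groups compared.

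At 6 h in the refractory period single genes of many kinds were higher, and as lists immediate early genes and inflammatory mediators held with an estimated correlation. The basement membrane gene lamb3.S rose from 1.97 ± 1.4 to 215 ± 49.1 CPM (log2 change 6.75 ± 0.82, adjusted p = 6.79e-06). The metalloproteinase genes mmp8.S (792 ± 102 against 13 ± 3.74 CPM, adjusted p = 4.54e-06) and mmp1.S (536 ± 155 against 2.15 ± 1.97 CPM, adjusted p = 2.36e-05) were higher, as was the AP-1 gene fosl1.L, 503 times its 0 h level (95% interval 139 to 4150, 1062 counts against 2). The leptin gene lep.L was at least 79.5-fold higher (252 counts against 0). Of signalling genes, pmepa1.L rose by 2.64 ± 0.25 (adjusted p = 2.35e-10), the activin subunit gene inhba.L by 3.10 ± 0.70 (adjusted p = 0.00296), the Notch ligand gene jag1.S by 2.51 ± 0.56 (adjusted p = 0.00264), lef1.L by 1.19 ± 0.18 (adjusted p = 3.28e-05) and the transcription factor gene sp8.L by 1.47 ± 0.23 (adjusted p = 2.06e-05). The homeolog lef1.S stood at 55.7 ± 13.6 CPM at 0 h and 56.2 ± 7.08 CPM at 6 h and was not called.

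Further single genes changed at refractory 6 h. Both ptgs2 homeologs rose (ptgs2.S by 1.73 ± 0.20, adjusted p = 4.36e-09), as did atf3.L, a stress-induced transcription factor gene (86.4 ± 27.1 against 11.1 ± 4.39 CPM, adjusted p = 3.31e-05), and the heme oxygenase gene hmox1.L (2.00 ± 0.46, adjusted p = 0.00403). Of epidermal genes, the tight junction gene cldn4.L (1.56 ± 0.19, adjusted p = 2.27e-06) and tgm1.L, a transglutaminase gene of the epidermal barrier (2.07 ± 0.33, adjusted p = 9.03e-06), rose. The retinoic acid-degrading enzyme gene cyp26a1.S fell by 1.64 ± 0.27 on the log2 scale (adjusted p = 2.07e-05) and the glucose-6-phosphatase gene g6pc1.3.L fell by 1.88 ± 0.36 (adjusted p = 0.000272).

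The refractory 6 h test called 520 genes (469 higher, 51 lower) with 32 libraries and 886 (718 higher, 168 lower) with 27, 519 of them in both. Of 77 immediate early genes 29 rose, and 44 when adjusted over the list alone. Immediate early genes together had a median of 0.96 (adjusted p = 1.7e-30, and adjusted p = 0.00759 with an estimated correlation). Of 28 inflammatory mediators 5 rose, and 10 when adjusted over the list alone. Inflammatory mediators had a median log2 change of 1.06 (adjusted p = 3.69e-11, and adjusted p = 0.000529 with an estimated correlation). Of 64 matrix protease genes 17 rose, and 19 when adjusted over the list alone. Matrix protease genes stood at a median log2 change of 0.15 (adjusted p = 1.15e-08, and adjusted p = 0.15 with an estimated correlation). Of 62 epidermis and goblet cell markers 16 rose, and 20 when adjusted over the list alone. Epidermis and goblet cell markers together had a median of 0.25 (adjusted p = 6.44e-14, and adjusted p = 0.107 with an estimated correlation). Of 43 tail tip epidermis genes 8 rose, and 10 rose and 2 fell when adjusted over the list alone. Tail tip epidermis genes had a median log2 change of 0.17 (adjusted p = 0.00384, and adjusted p = 0.52 with an estimated correlation). The list of cell cycle genes tested lower with none of 96 called (median -0.30, adjusted p = 0.000213, and adjusted p = 0.0829 with an estimated correlation), and so did oxidative phosphorylation with none of 89 called (median -0.25, adjusted p = 0.000115, and adjusted p = 0.59 with an estimated correlation). Of 29 erythroid markers 1 fell, and 3 when adjusted over the list alone (median -0.82, adjusted p = 7.33e-07, and adjusted p = 0.193 with an estimated correlation). Among 48 heat shock and endoplasmic reticulum stress genes 4 rose, among them the stress transcription factor gene atf4.L (0.46 ± 0.10, adjusted p = 0.00306), and the list did not pass (adjusted p = 0.248). Of the lists, 8 passed upward and 5 downward and 2 held with an estimated correlation, and with 27 libraries 7 and 5 passed and 5 held. In those 27, 38 of 78 immediate early genes and 22 of 62 epidermis and goblet cell markers rose. Without 6 h B 342 genes were called, and the other omissions gave up to 506.

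Few genes were called as different between the periods in their 6 h response, which does not show that the other genes responded alike. The mucin gene muc1.S went from 148 ± 9.05 to 1401 ± 244 CPM in the refractory period, where the regeneration groups stood at 105 ± 28.7 CPM at 0 h and 130.5 ± 9.99 CPM at 6 h (difference of log2 changes 2.93 ± 0.23, adjusted p = 1.77e-11). The FGF-binding protein gene fgfbp1.S went from 9.63 ± 1.9 to 55.0 ± 10.3 CPM in refractory tails, beside 18.3 ± 4.19 and 11.6 ± 4.35 CPM in regeneration tails (3.17 ± 0.46, adjusted p = 1.34e-05), and the chloride channel gene clic3.S from 88.0 ± 9.31 to 394 ± 12.1 CPM, beside 102 ± 10.6 and 132 ± 35.6 CPM (1.79 ± 0.21, adjusted p = 2.74e-08). In the other direction g6pc1.3.L fell in refractory tails from 25.0 ± 6.1 to 6.80 ± 2.57 CPM, beside 11.3 ± 7.57 CPM at 0 h and 30.4 ± 10.8 CPM at 6 h in regeneration tails (-3.27 ± 0.49, adjusted p = 2.61e-05).

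The test of the 6 h difference called 13 genes, 12 with the larger change upward in refractory tails and 1 downward. With 27 libraries it called 58 (44 and 14), including all 13, and with DESeq2's size factors 17 (13 and 4). The inflammatory mediators differed as a list (median 0.71, adjusted p = 6.85e-05, and adjusted p = 0.0225 with an estimated correlation), with 1 of 28 members called and 2 when adjusted over the list alone. Other named genes of this difference were ptgs2.L (2.08 ± 0.39, adjusted p = 0.0153) and tgm1.L (2.34 ± 0.47, adjusted p = 0.0102), whose calls were both lost without refractory 0 h B (adjusted p = 0.0517 each), that of ptgs2.L also without regeneration 6 h A (adjusted p = 0.0643). The calls of muc1.S, fgfbp1.S, clic3.S and g6pc1.3.L remained under each omission. Epidermis and goblet cell markers differed upward with 2 of 62 members called, and 9 higher and 1 lower when adjusted over the list alone (median 0.12, adjusted p = 0.00521, and adjusted p = 0.596 with an estimated correlation). Erythroid markers differed downward with none of 29 called, and 11 lower and 1 higher when adjusted over the list alone (median -1.51, adjusted p = 3.58e-10, and adjusted p = 0.0998 with an estimated correlation). At 0 h these markers already stood higher in refractory tails (median log2 difference 0.81). Of the lists, 3 passed upward and 2 downward and 1 held with an estimated correlation, and with 27 libraries 4 and 2 passed and 1 held. In those 27, 9 of 62 epidermis and goblet cell markers were called, all higher. Across the 538 genes called in either period at 6 h the changes correlated at r = 0.678, and at r = 0.223 over all genes (Spearman 0.162), and 88.7% of the called genes had the same sign. Of the genes called higher 38 were shared, where independent lists would share 1.04. Without regeneration 6 h C the correlation over all genes was 0.178.

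**Figure D3:**
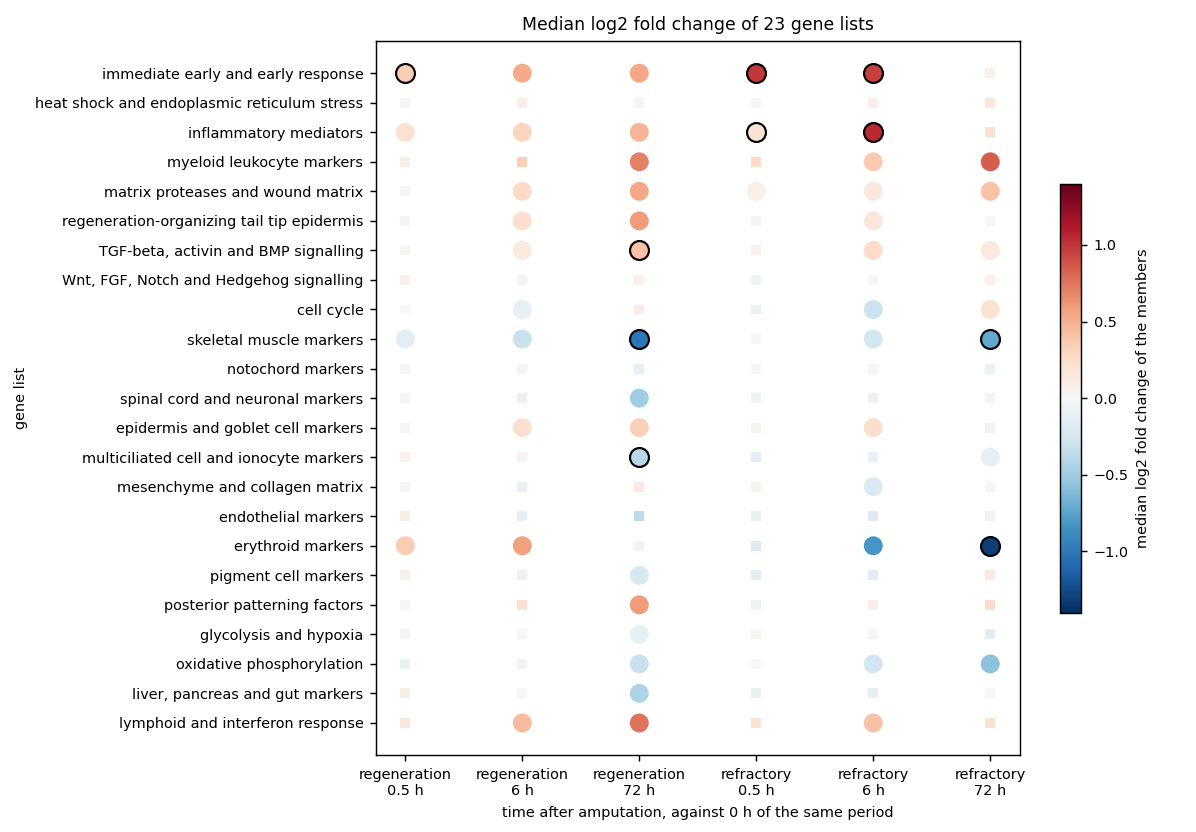
Median log2 change of the 23 gene lists in the 6 comparisons of a later time with 0 h, with large circles for lists that passed at an adjusted p under 0.05, small squares for those that did not, and a black outline where the call held with an estimated correlation. Skeletal muscle markers had the lowest median of regeneration 72 h at -1.02, and immediate early genes the highest of refractory 0.5 h at 0.99.

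At 72 h in the regeneration period, muscle genes were lower as a list, and single tail tip, notochord and matrix genes were higher. Of tail tip genes, lef1.L rose from 141 ± 8.37 to 326 ± 39.6 CPM (log2 change 1.22 ± 0.18, adjusted p = 1.84e-05), sp8.L rose by 0.99 ± 0.22 (adjusted p = 0.00281) and the phospholipid transfer protein gene pltp.L rose from 47.9 ± 8.56 to 173 ± 35.7 CPM (adjusted p = 5.3e-08). The homeolog lef1.S rose from 65.5 ± 9.81 to 103 ± 16.3 CPM, a call lost in 4 of 8 omissions with adjusted p up to 0.131. The notochord transcription factor homeologs not.L (3.79 ± 0.64, adjusted p = 3.13e-05) and not.S (4.58 ± 0.71, adjusted p = 0.00016) and the notochord matrix gene emilin3.L (2.80 ± 0.40, adjusted p = 4.58e-06) rose, as did the posterior patterning gene hoxa13.L (2.01 ± 0.41, adjusted p = 0.00059). Of matrix genes, mmp9.2.S held 751 counts against 1 (ratio 663, 95% interval 119 to 26200, adjusted p = 0.000427), fibronectin fn1.S rose by 1.22 ± 0.21 (adjusted p = 0.000524), and tgfbi.L, a TGF-beta-induced matrix gene, rose from 445 ± 60.5 to 1382 ± 111 CPM (adjusted p = 4.31e-05).

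Muscle genes fell. Tropomyosin tpm2.L fell from 697 ± 67.8 to 351 ± 27.8 CPM (log2 change -0.99 ± 0.11, adjusted p = 6.78e-10), as did the sarcomere gene myoz2.S (-1.28 ± 0.14, adjusted p = 1.25e-09) and the muscle glycogen phosphorylase gene pygm.S (-2.19 ± 0.35, adjusted p = 0.0002). Of metabolic genes, the glycolytic genes aldoa.L (6739 ± 1609 to 2720.0 ± 419 CPM, adjusted p = 3.1e-06) and ldha.S (-1.23 ± 0.16, adjusted p = 1.2e-07) were lower, and the respiratory chain gene cyc1.S was lower by a log2 change of -0.57 ± 0.10 (adjusted p = 0.000133). Lower too were the neuronal gene stmn3.S (-0.76 ± 0.16, adjusted p = 0.000692), the radial glia gene fabp7.L (-1.02 ± 0.21, adjusted p = 0.000852) and the erythrocyte ankyrin homeologs ank1.L and ank1.S.

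The regeneration 72 h test called 818 genes (345 higher, 473 lower) with 32 libraries and 1111 (459 higher, 652 lower) with 27, 741 of them in both. Without 72 h B 493 genes were called, and the other omissions gave up to 733. Of 86 muscle markers 46 fell, and 55 when adjusted over the list alone. Muscle markers stood at a median log2 change of -1.02 (adjusted p = 1.24e-61, and adjusted p = 0.000529 with an estimated correlation). Of 53 TGF-beta, activin and BMP genes 9 rose, and 14 when adjusted over the list alone. TGF-beta, activin and BMP genes together had a median of 0.41 (adjusted p = 3.98e-06, and adjusted p = 0.00169 with an estimated correlation). Of 54 multiciliated cell and ionocyte markers 2 fell, and 2 when adjusted over the list alone. Multiciliated cell and ionocyte markers had a median log2 change of -0.39 (adjusted p = 0.000204, and adjusted p = 0.0145 with an estimated correlation). These 3 of the 16 lists that passed held with an estimated correlation. Inflammatory mediators, also among the 16, passed upward with a median log2 change of 0.475 and did not hold. With 27 libraries 9 passed upward and 7 downward, and 9 held, tail tip epidermis (adjusted p = 0.0061) and glycolysis and hypoxia (adjusted p = 0.0061) among them.

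Of 43 tail tip epidermis genes 14 rose, and 18 when adjusted over the list alone. Tail tip epidermis genes stood at a median log2 change of 0.59 (adjusted p = 8.59e-14, and adjusted p = 0.079 with an estimated correlation). Of 62 epidermis and goblet cell markers 6 rose and 1 fell, and 14 rose and 2 fell when adjusted over the list alone (median 0.34, adjusted p = 7.14e-05, and adjusted p = 0.436 with an estimated correlation). Of 64 matrix protease genes 15 rose, and 23 rose and 3 fell when adjusted over the list alone. Matrix protease genes together had a median of 0.54 (adjusted p = 9.9e-08, and adjusted p = 0.176 with an estimated correlation). Of 41 myeloid leukocyte markers 2 rose, and 3 when adjusted over the list alone. Myeloid markers had a median log2 change of 0.70 (adjusted p = 0.000223, and adjusted p = 0.079 with an estimated correlation). Of 27 lymphoid and interferon response genes 2 rose, and 4 when adjusted over the list alone. Lymphoid and interferon genes stood at a median log2 change of 0.76 (adjusted p = 4.92e-05, and adjusted p = 0.145 with an estimated correlation). Of 46 posterior patterning genes 2 rose, and 7 when adjusted over the list alone. Posterior patterning genes together had a median of 0.60 (adjusted p = 1.2e-05, and adjusted p = 0.0829 with an estimated correlation). Of 93 spinal cord and neuronal markers 6 fell, and 8 when adjusted over the list alone. Spinal cord and neuronal markers had a median log2 change of -0.50 (adjusted p = 2.9e-09, and adjusted p = 0.157 with an estimated correlation). Of 55 glycolysis and hypoxia genes 9 fell and 1 rose, and 14 fell and 4 rose when adjusted over the list alone. Glycolysis and hypoxia genes stood at a median log2 change of -0.11 (adjusted p = 0.00302, and adjusted p = 0.338 with an estimated correlation). Of 89 oxidative phosphorylation genes 6 fell, and 8 when adjusted over the list alone (median -0.31, adjusted p = 4.32e-07, and adjusted p = 0.451 with an estimated correlation). Of 77 immediate early genes 8 rose, and 19 when adjusted over the list alone (median 0.54, adjusted p = 3.4e-08, and adjusted p = 0.176 with an estimated correlation). Of 25 pigment cell markers 2 fell, dct.L and pmel.L of the melanin pathway, and 6 fell and 1 rose when adjusted over the list alone. Pigment cell markers together had a median of -0.23 (adjusted p = 0.0176, and adjusted p = 0.0738 with an estimated correlation). Of 37 liver, pancreas and gut markers 3 fell, and 3 when adjusted over the list alone. Liver, pancreas and gut markers had a median log2 change of -0.43 (adjusted p = 5.43e-05, and adjusted p = 0.451 with an estimated correlation). With 27 libraries 21 of 90 oxidative phosphorylation genes fell (median -0.45, adjusted p = 9.17e-13, and adjusted p = 0.169 with an estimated correlation), as did 51 of 87 muscle markers. In that fit 18 of 78 immediate early genes rose, 11 epidermis and goblet cell markers rose and 4 fell of 62, 17 matrix protease genes rose and 3 fell of 64, and 3 glycolysis and hypoxia genes rose and 13 fell of 56. In the libraries of the normalized tables, genes of liver, pancreas and gut summed to 2661 ± 279 CPM at 72 h (n = 4) and 3201 ± 532 CPM at 0 h (n = 3), and retina and lens genes to 1583 ± 186 and 1826 ± 191 CPM, values that were not tested.

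Lists that did not pass at regeneration 72 h were Wnt, FGF, Notch and Hedgehog signalling (9 of 104 members higher, adjusted p = 0.0849), notochord markers (7 higher and 4 lower of 45, median -0.13 and mean 0.35, adjusted p = 0.822), mesenchyme and collagen matrix (5 higher and 4 lower of 91, adjusted p = 0.138), endothelial markers (0 of 37, adjusted p = 0.101) and cell cycle genes (adjusted p = 0.194). Nor did heat shock and endoplasmic reticulum stress genes (4 of 48 lower, adjusted p = 0.627) and erythroid markers (2 of 29 lower, adjusted p = 0.379). Endothelial markers passed in none of the 10 contrasts. The replication gene top2a.L was called in none either, at 188 ± 9.86 CPM at 0 h and 221 ± 17.7 CPM at 72 h in regeneration tails, and neither was wnt5a.S (16.1 ± 3.25 and 26.2 ± 3.7 CPM).

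At 72 h in the refractory period, erythroid and muscle genes were lower than at 0 h as lists, and single matrix and wound genes were higher. The protease gene mmp13l.L was at least 42.4-fold higher (160 counts against 0, adjusted p = 0.000623) and mmp9.2.S 171 times its 0 h level (95% interval 47.4 to 1410, 430 counts against 2). Fibronectin fn1.S rose by 1.54 ± 0.21 (adjusted p = 0.000173), tgfbi.L by 1.51 ± 0.23 (adjusted p = 0.000531), clu.L by 4.25 ± 0.51 (adjusted p = 4.92e-08) and the Wnt inhibitor gene sfrp2.L from 59.7 ± 8.8 to 406 ± 243 CPM (adjusted p = 2.35e-05). Of the globin genes, hbd.S went from 5609 ± 3901 to 433 ± 65.3 CPM (-3.70 ± 0.72, adjusted p = 0.0052) and hba3.L from 3593 ± 2495 to 248 ± 34 CPM (adjusted p = 0.00649). The gene ouro1.S, whose protein is a larval tail skin antigen, fell from 112 ± 44.9 to 3.33 ± 1.74 CPM (adjusted p = 4.85e-06). Among muscle genes myoz1.L was at least 29.7-fold lower (0 counts against 71 at 0 h, adjusted p = 0.00148) and troponin tnnc2.S fell by 1.30 ± 0.16 (adjusted p = 1.18e-06). Tail tip gene lef1.L stood at 192 ± 58.7 CPM against 122 ± 16.6 at 0 h, short of the threshold (adjusted p = 0.0532). In the 27 libraries, which lack refractory 72 h A, lef1.L stood at 216 ± 35.1 CPM (n = 3) against 122 ± 16.8 CPM (n = 4).

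The refractory 72 h test called 350 genes (127 higher, 223 lower) with 32 libraries and 747 (347 higher, 400 lower) with 27, 332 of them in both. The count was 228 without 72 h B, 224 without 72 h C, 180 without 0 h D and 231 without 72 h D, and at most 386, without 72 h A. Of 86 muscle markers 30 fell, and 42 when adjusted over the list alone. Muscle markers stood at a median log2 change of -0.73 (adjusted p = 9.54e-33, and adjusted p = 0.0128 with an estimated correlation). Of 29 erythroid markers 12 fell, and 17 when adjusted over the list alone. Erythroid markers together had a median of -1.32 (adjusted p = 4.86e-24, and adjusted p = 0.0115 with an estimated correlation). Of 89 oxidative phosphorylation genes 14 fell, and 38 when adjusted over the list alone. Oxidative phosphorylation genes had a median log2 change of -0.57 (adjusted p = 1.69e-25, and adjusted p = 0.0931 with an estimated correlation). Of 64 matrix protease genes 10 rose, and 18 when adjusted over the list alone. Matrix protease genes stood at a median log2 change of 0.41 (adjusted p = 2.83e-08, and adjusted p = 0.168 with an estimated correlation). Of 41 myeloid markers 1 rose, the chemokine receptor gene cxcr4.S, a call lost in 5 of 8 omissions with adjusted p up to 0.443 (median 0.84, adjusted p = 7.85e-05, and adjusted p = 0.0738 with an estimated correlation). With an estimated correlation 2 lists held, and with 27 libraries 7 passed upward and 4 downward and 8 held. In those 27, 37 of 87 muscle markers and 23 of 90 oxidative phosphorylation genes fell, and 19 of 64 matrix protease genes rose. Immediate early genes had 10 higher and 2 lower of 78, epidermis and goblet cell markers 6 and 1 of 62, heat shock and endoplasmic reticulum stress 5 and 2 of 48 and glycolysis and hypoxia 2 and 7 of 56. Notochord markers had 6 and 6 of 45 and mesenchyme and collagen matrix 4 and 4 of 92. With 32 libraries heat shock and stress genes had 0 higher and 1 lower, glycolysis 1 and 2, notochord 4 and 3, and epidermis and mesenchyme 0 and 0. Immediate early genes (1 of 77 higher, adjusted p = 0.321) and tail tip epidermis (1 of 43 lower, adjusted p = 0.989) did not pass.

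The changes from 0 h to 72 h differed between the periods in single genes of several kinds. Without unamputated tails at 72 h, normal development cannot be separated from the response to amputation. Of the genes below, pltp.S, ckb.L, ldha.S, thdl18.S and thdl20.S, but not fbln1.L, were also called between the periods at 0 h. Each differed there in the direction that regeneration tails moved by 72 h. The tail tip gene pltp.S fell in refractory tails from 106 ± 52.2 to 27.9 ± 8.32 CPM, while regeneration tails stood at 37.5 ± 14.6 CPM at 0 h and 97.0 ± 9.92 CPM at 72 h (difference -3.30 ± 0.47, adjusted p = 0.000265). The connective tissue gene fbln1.L stood at 724 ± 69.2 and 745 ± 116 CPM in refractory tails and rose from 615 ± 61.2 to 1102 ± 60 CPM in regeneration tails (-0.80 ± 0.14, adjusted p = 0.000228). The brain-type creatine kinase gene ckb.L (1.23 ± 0.19, adjusted p = 9.44e-05) and the lactate dehydrogenase gene ldha.S (1.2 ± 0.23, adjusted p = 0.00157) fell in regeneration tails, beside refractory changes of -0.25 ± 0.14 (adjusted p = 0.573) and -0.04 ± 0.16 (adjusted p = 0.982) that were not called. The gene thdl18.S, at 155 ± 90.7 and 26.1 ± 17.9 CPM in refractory tails, rose from 0.72 ± 0.49 to 142 ± 40 CPM in regeneration tails (-10.03 ± 1.28, adjusted p = 9.44e-05), and for thdl20.S the difference was -7.79 ± 0.98 (adjusted p = 9.25e-05), fitted values that rest on few counts at regeneration 0 h.

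The test of the 72 h difference called 99 genes (25 with a positive and 74 with a negative difference of refractory minus regeneration) with 32 libraries and 178 (80 and 98) with 27, 89 of them in both. Without regeneration 72 h B 59 were called, and the omissions gave up to 138. Tail tip epidermis genes differed as a list with 3 of 43 members lower, pltp.S, pltp.L and col14a1.S, of which pltp.L and col14a1.S lost their calls in 8 and 11 of 16 omissions, and 8 when adjusted over the list alone. Together the tail tip genes had a median difference of -0.56 (adjusted p = 5.58e-11, and adjusted p = 0.108 with an estimated correlation). Erythroid markers also differed, with 4 of 29 members lower and 14 when adjusted over the list alone. Erythroid markers had a median difference of -1.38 (adjusted p = 4.25e-12, and adjusted p = 0.079 with an estimated correlation). At 0 h these markers already stood higher in refractory tails (median log2 difference 0.81). The difference in response cannot be separated from that start. Muscle markers differed upward (median 0.37, adjusted p = 2.64e-07, and adjusted p = 0.288 with an estimated correlation), with 1 of 86 members called, myoz1.L, which was lower, and 5 higher and 1 lower when adjusted over the list alone. Spinal cord and neuronal markers differed upward with none of 93 called (median 0.44, adjusted p = 5.73e-07, and adjusted p = 0.261 with an estimated correlation). Epidermis and goblet cell markers differed downward with 1 of 62 called, and 1 higher and 6 lower when adjusted over the list alone (median -0.28, adjusted p = 0.000149, and adjusted p = 0.451 with an estimated correlation). Oxidative phosphorylation differed downward with none of 89 called (median -0.24, adjusted p = 0.00173, and adjusted p = 0.701 with an estimated correlation), and glycolysis and hypoxia genes did not pass (2 higher and 1 lower of 55, adjusted p = 0.275). Immediate early genes differed downward with none of 77 called, and 1 when adjusted over the list alone (median -0.34, adjusted p = 8.58e-05, and adjusted p = 0.375 with an estimated correlation). None of the 13 lists that passed held with an estimated correlation. With 27 libraries 4 passed upward and 3 downward, of which 2 held: tail tip epidermis (adjusted p = 0.0158) and erythroid markers (adjusted p = 0.0483). Across the 986 genes called in either period at 72 h the changes correlated at r = 0.439, and at r = 0.182 over all genes (Spearman 0.17), and 78.5% of the called genes had the same sign. Shared calls were 63 higher and 110 lower, where independent lists would share 2.06 and 4.97, and 9 genes were called in opposite directions.

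At 0 h refractory tails differed from regeneration tails in single genes of several kinds. The larval skin antigen genes ouro1.S and ouro2.L were higher in refractory tails: ouro1.S at 112 ± 44.9 against 0.37 ± 0.42 CPM (log2 difference 8.04 ± 0.73, adjusted p = 4.16e-07) and ouro2.L at least 72.7-fold (172 counts against 0, adjusted p = 1.77e-05). Higher too were thdl17.L, at 322 times the regeneration level (95% interval 110 to 1560, 761 counts against 3), the keratin gene krt62.L (116 ± 62.2 against 3.93 ± 3.34 CPM, adjusted p = 0.000158), the tendon gene tnmd.S (at least 23.7-fold, 56 counts against 0, adjusted p = 0.00352) and the hypoxia-responsive gene ndrg1.S (146 ± 21.5 against 58.7 ± 11.8 CPM, adjusted p = 3.82e-07). The mitochondrial chaperone gene hspa9.L was lower in refractory tails (44.3 ± 9.03 against 87.9 ± 15.4 CPM, adjusted p = 0.00299), as was sh3rf2.S (-1.78 ± 0.34, adjusted p = 0.00252). The globin gene hbd.S stood at 5609 ± 3901 against 628 ± 269 CPM (adjusted p = 0.0282), a call lost in 5 of 8 omissions with adjusted p up to 0.14.

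The 0 h test called 142 genes (83 higher and 59 lower in refractory tails) with 32 libraries and 520 (199 and 321) with 27, 140 of them in both. The count was 49 without regeneration 0 h B, 77 without regeneration 0 h C, 87 without regeneration 0 h D and 70 without refractory 0 h D, and at most 207, without regeneration 0 h A. Of 48 heat shock and endoplasmic reticulum stress genes 7 were lower, and 10 when adjusted over the list alone. Heat shock and endoplasmic reticulum stress genes stood at a median log2 difference of -0.32 (adjusted p = 9.35e-09, and adjusted p = 0.0768 with an estimated correlation). Of 29 erythroid markers 4 were higher, and 14 higher and 1 lower when adjusted over the list alone. Erythroid markers together had a median difference of 0.81 (adjusted p = 3.22e-11, and adjusted p = 0.0829 with an estimated correlation). Of 77 immediate early genes 3 were higher, and 8 when adjusted over the list alone. Immediate early genes had a median log2 difference of 0.42 (adjusted p = 3.49e-09, and adjusted p = 0.148 with an estimated correlation). Liver, pancreas and gut markers tested higher with none of 37 called (median 0.18, adjusted p = 0.0165, and adjusted p = 0.701 with an estimated correlation). In the libraries of the normalized tables these genes summed to 4118 ± 394 CPM at refractory 0 h (n = 4) and 3201 ± 532 CPM at regeneration 0 h (n = 3), and retina and lens genes to 2081 ± 135 and 1826 ± 191 CPM, values that were not tested. Epidermis and goblet cell markers did not pass at 0 h (1 higher and 2 lower of 62, median -0.08, adjusted p = 0.25). Of the lists, 7 passed upward and 3 downward and none held with an estimated correlation. With 27 libraries 7 and 4 passed and 2 held, immediate early genes (adjusted p = 0.0261) and heat shock and endoplasmic reticulum stress (adjusted p = 0.00211). In those 27, 10 of 78 immediate early genes were higher, 1 epidermis and goblet cell marker was higher and 14 lower of 62, and 1 tail tip epidermis gene was higher and 6 lower of 44. Muscle markers had 2 higher and 3 lower of 87, and glycolysis and hypoxia genes 3 and 7 of 56. With 32 libraries tail tip epidermis had 1 and 0, muscle markers 0 and 0 and glycolysis 2 and 1. Period cannot be separated here from the age of the embryos, or from a clutch or sequencing run if these differed between the sets.

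**Figure D4:**
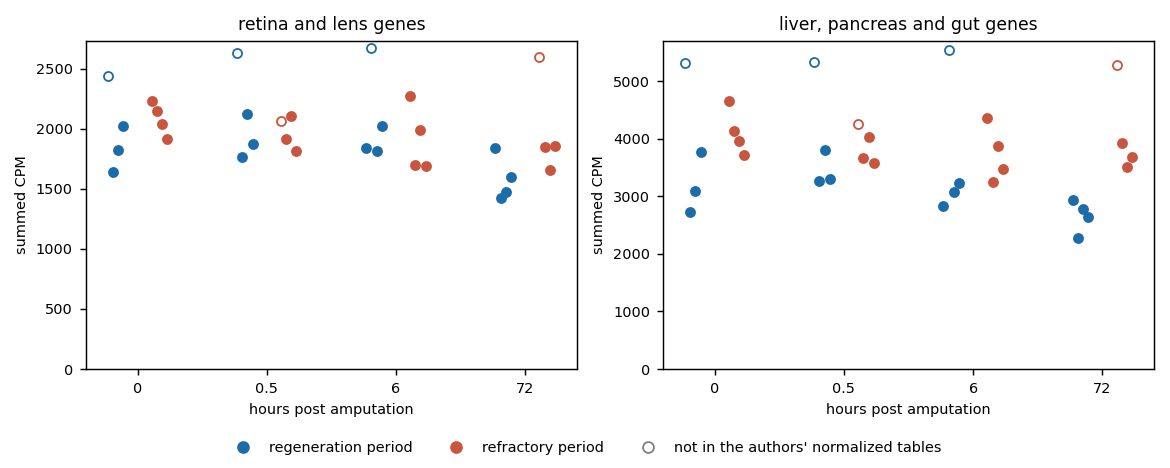
Summed CPM of retina and lens genes and of liver, pancreas and gut genes in each of the 32 libraries by hours after amputation, with regeneration in blue, refractory in red and open circles for the 5 libraries absent from the authors' normalized tables. The retina and lens sum ran from 1427 to 2269 CPM in the 27 libraries of those tables and from 2436 to 2669 CPM in 4 of the other libraries.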

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

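The tests of low complexity, of swapped labels and of outside tissue were chosen only after the result was seen. Of 160 tests of 4 libraries for 1 value far from the other 3 (gap over range above Dixon's critical value, which chance exceeds in about 5% of groups), 9 passed. Regeneration 6 h B was apart in genes detected at equal depth (0.836; 20869 against 22807 to 23186) and in the liver, pancreas and gut sum (0.854; 5538 against 2831 to 3225 CPM). Regeneration 0 h A was apart in the share of its 10 most counted genes (0.976; 9.67% against 12.399% to 12.465%). Refractory 72 h A was low in atf3.L (0.945; 4.42 against 13.4 to 13.9 CPM) and in egr1.L (0.924; 139 against 202 to 207 CPM). The other values were top2a.L in regeneration 0.5 h A (0.968; 220.4 against 200.03 to 200.67 CPM), lef1.L in regeneration 0.5 h C (0.877; 155 against 129 to 132 CPM), mmp8.L in refractory 6 h B (0.885; 189 against 65.5 to 79.7 CPM) and wnt5a.S in refractory 72 h C (0.84; 31.2 against 9.79 to 13.2 CPM).

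By the test of the difference itself, 8 named genes responded differently in the periods at 6 h. The differences of log2 changes, refractory minus regeneration, were 3.17 for fgfbp1.S, 2.93 for muc1.S, 2.34 for tgm1.L, 2.08 for ptgs2.L, 1.93 for lipg.L, 1.79 for clic3.S, 1.61 for itgb4.L and -3.27 for g6pc1.3.L. Single omissions ended the calls of itgb4.L in 10 and of lipg.L in 9 of 16 cases.

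At 72 h the differences were positive for ocm4.5.L (2.24), odf3.L (1.88), aldoc.L (1.24), ckb.L (1.23), ldha.S (1.2) and pmel.L (1.19). They were negative for the skin genes thdl18.S (-10.03), ouro2.L (-8.28), thdl20.S (-7.79), thdl17.L (-6.77) and upk1b.S (-1.76), and for the globin genes hbg2.L (-9.39), hbd.S (-4.67) and hba2.L (-4.67). They were also negative for myoz1.L (-7.54), tnmd.L (-3.45), pltp.S (-3.30), cyp26a1.S (-1.57), ndrg1.S (-1.44), pltp.L (-1.33), col14a1.S (-1.19), fbln1.L (-0.80) and mfap2.S (-0.76). The fitted values of thdl17.L, thdl18.S, thdl20.S, ouro2.L, hbg2.L and myoz1.L rest on groups with almost no counts and are no bounds. Without 1 of the 16 libraries the calls of aldoc.L, ckb.L, ldha.S, thdl18.S, thdl20.S, upk1b.S, hbg2.L, pltp.S, ndrg1.S and fbln1.L remained, and each of the others was lost at least once.

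Genes listed only in the refractory table were not part of any comparison, and 7 of them held at least 30 counts at a later time and at most 3 at 0 h. These were dram1.L (30 counts), krt61.L (30), ifit1b.L (44, 40 of them in 1 library), LOC108695500 (41) and LOC121402051 (104) at 72 h, and LOC121393934 (39) and LOC121395656 (73, 68 of them in 1 library) at 6 h.

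Regeneration 0 h A, regeneration 0.5 h A, regeneration 6 h B and refractory 72 h A resembled each other more than their groups (lowest correlation of centred log2 CPM between them 0.46 across 7281 genes, highest with the other 28 libraries 0.259), and the 3 amputation libraries among them had a median of 11.5%, -16% and 14.4% of their groups' log2 response. Over 447 genes called at 0 h between the periods in the 27 libraries, the 3 regeneration libraries lay 85.4% to 86.5% of the way from the regeneration to the refractory 0 h mean, where the 13 other regeneration libraries lay at -10% to 43%. The refractory 0 h libraries and regeneration 0 h B, C and D chose these genes and set both ends of the scale, so their own places are no evidence. A swap of labels between the periods is argued against for the refractory libraries of later times, which lay at 73.8% to 102% with none out of place. RNA of 1 shared pool and separate samples cannot be told apart, because refractory 72 h A lay at 84.4%, near the other 3 but also near the 73.8% to 81.7% of its group. The 3 amputation libraries had 21020, 20869 and 21691 genes detected at equal depth, fewer than each other library of the 3 groups. Low complexity alone stays undecided as the cause of their weak response. It predicts the fewer detected genes, but not low shares in genes of at least 20 CPM. There the upper quartiles of the share were 37.7%, 21.3% and 43.3%. The other libraries of these groups had medians of 91.4% to 106.1%. They helped choose these genes and set the full response, so their own medians are no evidence. Choosing the genes without the 3 amputation libraries can also lower the shares of these 3. A single wrong label and a swap with an outside sample stay open, and no biological explanation was tested.

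Genes of retina and lens, of forebrain and midbrain and of liver, pancreas and gut had counts in libraries labelled tail: rho.S, the rod opsin gene, stood at 146.5 to 342.3 CPM in the 27 libraries and ttr.S, a plasma protein gene of liver, at 444.3 to 1000.4 CPM, and in the 4 libraries named above rho.S stood at 383.8 to 417.3 and ttr.S at 1127.5 to 1271.4 CPM. Other ranges overlapped: rho.L reached 313.5 CPM in the 27 libraries and began at 306.8 in the 4, crx.S reached 245.2 and began at 231.2, and the forebrain and midbrain sum reached 589 and began at 587 CPM. Carry-over between the 32 libraries is argued against, since the highest retina and lens sum was 1.87 times the lowest and no library could serve as a source. RNA from outside the tail that reaches each library from 1 source is a candidate explanation: over the 27 libraries the deviations of the retina and lens sum from group means followed those of the liver, pancreas and gut sum (r = 0.888, Spearman 0.902, permutation p = 1e-05 each, the smallest that 100000 permutations can give, and r = 0.871 without the 2 farthest libraries), beside r = 0.608 for forebrain with liver and 0.44 for retina with forebrain. Of the measured genes 0 of 47 for retina and lens, 8 of 24 for forebrain and midbrain (9.08% to 21.4% of the sum) and 0 of 37 for liver were marked as also expressed in tail tissue such as spinal cord, and none is in another list. The marking was made by hand and not from expression data, so expression of the other genes in tail cells is not ruled out. Whether such RNA entered at dissection, at extraction or later was not tested, and a biological source in the tail itself stays open and untested.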

How the results depend on the processing

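The fit of 27 libraries was the only alternative added after seeing the data. Counts below follow the order regeneration 0.5, 6 and 72 h, refractory 0.5, 6 and 72 h, difference at 0.5, 6 and 72 h, and 0 h, of which 13, 58, 818, 28, 520, 350, 0, 13, 99 and 142 genes were called. DESeq2's size factors, no low-count filter, the filter on CPM (which keeps more genes than filterByExpr), homeologs summed and the replicate letter as a block kept every count within 1.5 times its value. With the letter as a block the counts were 13, 44, 824, 29, 527, 332, 0, 15, 114 and 147. The letters paired samples weakly at most: of 48 pairs with the same letter within a period, 1 correlated above 0.1 (median 0.012), and 12 of 32 libraries correlated best with their own letter. A weak shared factor is not ruled out, as the labels do not say what a letter marks. An adjusted p under 0.01 gave 5, 16, 451, 18, 311, 171, 0, 7, 48 and 71 genes, fewer by construction, and kept 66.2% of the named calls. A 2-fold minimum gave 37 at regeneration 6 h, 441 at regeneration 72 h, 209 at refractory 72 h and 88 at 0 h, also by construction.

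For the other changes the cause was not tested. The Wald test of DESeq2 gave 20 at regeneration 0.5 h, 110 at regeneration 6 h, 43 for the 6 h difference and 189 for the 72 h difference. Fitting only the groups compared gave 4, 2 and 54 at regeneration 0.5 h, regeneration 6 h and refractory 0.5 h, and fitting the period's 16 libraries gave 2, 17 and 50. The 27 libraries gave 28, 323, 66, 886 and 747 at regeneration 0.5 and 6 h and refractory 0.5, 6 and 72 h, 58 and 178 for the 6 and 72 h differences and 520 at 0 h. Over called genes instead of all genes, the correlations of the periods' changes were 0.457 instead of 0.036, 0.678 instead of 0.223 and 0.439 instead of 0.182. With the filter on CPM the one over all genes at 6 h was 0.107 instead of 0.223. With an estimated correlation 11 instead of 86 of 230 list tests passed. With homeologs summed, gapdh.L turned to -0.164 at refractory 6 h and -0.428 at refractory 72 h, and ina.L to 0.144 at refractory 72 h.

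Leaving out 1 library in turn gave 4 (regeneration 0 h B) to 21 genes (0.5 h A) at regeneration 0.5 h, 12 (6 h C) to 229 (6 h B) at 6 h and 493 (72 h B) to 733 (0 h A) at 72 h. In the refractory period it gave 18 (0 h A) to 26, 342 (6 h B) to 506 and 180 (0 h D) to 386 (72 h A). It gave 0 to 1, 9 to 19 and 59 (regeneration 72 h B) to 138 (refractory 0 h A) for the differences, and 49 (regeneration 0 h B) to 207 (regeneration 0 h A) at 0 h. The correlation over all genes at 6 h ran from 0.178 (regeneration 6 h C) to 0.23. Of 281 named calls 164 remained under every omission, 117 were lost in at least 1 and 0 turned, and single omissions kept 42.4% to 97% of the calls they touch. For single genes and single list tests together, over all alternatives, 7678 values kept their direction and side of the threshold, 967 lost the call and 55 gained it. Of the rest, 124 changed direction without a call in either setting and 3 changed direction with a call. Depth limits genes near 1.61 CPM in the shallowest library.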

Other observations

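The fit of the 27 libraries, the tests of heat shock genes in it and the genes named here from it were chosen only after the result was seen. In that edgeR fit, tail tip and epidermal genes rose at 6 h in the regeneration period: the homeobox genes msx1.S (241 to 389 CPM, log2 change 0.69 ± 0.13 SE, adjusted p = 0.000177) and dlx3.L (109 to 194 CPM, adjusted p = 0.00028), and the epithelial genes trim29.S (100.1 to 232 CPM, adjusted p = 2.76e-08) and epcam.S (57.1 to 144 CPM, adjusted p = 4.75e-08). In that fit dlx3.L stood at 93.4 CPM at 0 h and 82.8 CPM at 6 h in refractory tails (difference of log2 changes -1.0 ± 0.21, adjusted p = 0.00727), and the collagen chaperone gene serpinh1.S differed in the same direction (-1.31 ± 0.29, adjusted p = 0.0257). Of posterior patterning genes, tbxt.L, the brachyury gene of notochord and tailbud, rose at refractory 72 h (0.90 to 11.2 CPM, adjusted p = 0.0114), as did hoxc13.L (18.4 to 43.2 CPM, adjusted p = 0.0143).

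The endoplasmic reticulum chaperone gene hspa5.L was lower at 0 h in refractory than in regeneration tails in the fit of 27 libraries, at 66.5 against 170 CPM (-1.35 ± 0.15, adjusted p = 1.27e-10). At 72 h hspa5.S stood at 190.1 CPM after 132 CPM in refractory tails and at 264 CPM after 366 CPM in regeneration tails (difference 1.0 ± 0.17, adjusted p = 5.57e-05). As a list, heat shock and endoplasmic reticulum stress genes were lower at 0 h with 9 of 48 members called (adjusted p = 1.36e-12, and adjusted p = 0.00211 with an estimated correlation). The Wnt inhibitor gene sfrp2.L went from 59.6 to 502 CPM in refractory and from 76.3 to 168 CPM in regeneration tails at 72 h (difference 1.94 ± 0.28, adjusted p = 5.72e-05). The goblet cell gene otogl2.L was lower at 0 h in refractory tails (8678 against 15847 CPM, adjusted p = 9.83e-07).

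Genes higher at 0 h in refractory than in regeneration tails overlapped with those that rose from 0 to 72 h in regeneration tails: 31 were called higher in both, 19 lower in both and 0 in opposite directions by edgeR, an overlap that shared control libraries favour by themselves. Among them were krt78.1.L, clu.L and rhcg.L (higher) and ldha.S, ckb.L and hspa9.L (lower). Both comparisons use the regeneration 0 h libraries, whose noise alone gives a covariance: over 14898 genes it was 0.0918, and at most 0.0712 in 100 simulations without effects, while the correlation was 0.342, below the simulated median of 0.498 (highest 0.514). The simulated libraries lack the structure of regeneration 0 h A, so noise of shared controls stays open as the cause. A hypothesis is that age of the embryos changes these genes, so that tails of the regeneration period may come to resemble older tails over 72 h. With separate regeneration 0 h libraries for each comparison, the covariance ran from -0.0081 to 0.0532 over 6 splits, where simulations without effects gave at most 0.0055, so age and the choice of control libraries cannot be told apart.

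Other splits of the same libraries were run for each count of called genes. At regeneration 72 h 1 of 35 splits, the real one with 818 genes, gave as many (highest other 162). The same held at refractory 0.5 h with 1 of 35 (28 genes, highest other 0) and at refractory 6 h with 1 of 35 (520 genes, highest other 3). It also held at refractory 72 h with 1 of 35 (350 genes, highest other 75) and at 0 h between the periods with 1 of 35 (142 genes, highest other 47). These splits argue against chance for these counts. They cannot exclude it, since 1 of 35 is the smallest share that 35 splits can give and was not adjusted over the contrasts. Of 100 splits drawn from 2450, 1 gave as many as the 99 genes of the 72 h difference (highest other 29). Splits of a difference exchange libraries between periods that already differed at 0 h. They test for any effect of period, so they cannot exclude chance for a difference in response. For the 6 h difference 4 of 100 drawn splits gave at least 13 genes (highest other 279), a share under 0.05 but too near it for 100 draws to exclude chance. Chance stays open at regeneration 0.5 h, where 2 of 35 splits gave at least 13 genes (highest other 42), and at regeneration 6 h, where 5 of 35 gave at least 58 (highest other 226). The 0.5 h difference had 0 genes, which all 100 splits reach by construction (highest other 323), so its splits say nothing about chance. Splits that call several times the real count point to a structure of the samples: the one with 226 genes put regeneration 0 h A and 6 h B together, and the one with 42 put 0 h A and 0.5 h A together. The one with 279 set regeneration 6 h A, C and D apart from 6 h B.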
